A study of Gallus gallus with 12 samples.

How the data were processed

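Total RNA of breast muscle from 12 chickens at day 42 was extracted, and 600 ng per sample was labelled with Cy3 and hybridised to Agilent chicken gene expression arrays, 1 sample per array, per the labels' protocols. The scanner files hold spot intensity per array, and per the file headers the processed signal was background-subtracted and spatially detrended by Agilent Feature Extraction 11.5.1.1 and was not normalized between arrays. Mean signal and median local background are intensity as scanned, per the file headers, and the same files hold 0 or 1 flags per spot. The authors also deposited log2 values for 28073 gene names. How they were made is not given in the sources used here. Set against the scanner signals, 92.5% of these values lay within 0.01 of the mean log2 signal of the gene name's probes after centring on the array, each array's 75th percentile was about 0, and array medians ranged from −2.746 to −2.585. They are therefore on a log2 scale, not centred per gene and higher for brighter spots, and how the other values were made stays unknown. The test the authors used is not given in the sources used here.

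Groups were taken from the sample titles, 6 control and 6 PHF. Each array had 45220 spots, 43803 of them not controls, and 43154 distinct probes. Control spots and spots marked as outliers were left out, spots of 1 probe were averaged, and no spot was saturated. The log2 processed signal minus the array's 75th percentile was used, and the 32535 probes (75.4%) well above background on at least 6 of the 12 arrays were tested; 27241 probes were well above background on every array. The reference table of gene names, made for assembly GRCg7b, was used for names only, with no coordinates. Of 11476 probes with a RefSeq accession, 10458 (91.1%) matched it and 1108 symbols were updated; other probes kept the array's name, and 12506 tested probes had no gene symbol. A gene with several probes was read by the probe with the highest mean over all arrays, and values in the text are those of that probe. Among the genes named by the rule below, other tested probes went the opposite way for PAPSS2, GUCA1B, PAX2, ACTN2, ATP5G1, MDH1, PSMD6, PSMD3, RPL8, RPL9, MYH11, ACTB, MB, GHR, FBXO32, TRIM63 and CPT1A, and so they did for HSPA5 and ATF4. For GHR this was 6 of 8 probes, with changes up to 0.49, and for PAX2 1 of 2, at 0.052.

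Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit on group, eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with data.table (version 1.17.8) for reading. The 32 gene lists, covering contraction, energy and lipid metabolism, stress responses, protein turnover, growth, immunity and markers of other cell types, were fixed before the data were examined, as were the tests and most alternatives. Lists were tested with camera at its preset correlation of 0.01, Benjamini-Hochberg over the 32 lists. Camera with an estimated correlation and fry were run beside it. Array measures were compared with an exact permutation test, two-sided. The spread between birds was the median log2 ratio of variances over probes, against 100 random splits of group-centred values. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

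Genes named in the text followed a rule fixed beforehand. Where fewer than 5 probes passed in a direction, the 10 genes of lowest p in that direction were named and said not to pass. From each called list, up to 4 members were named, those past the threshold first and then those of lowest p. A fixed panel of muscle, growth, lipid, antioxidant and immune genes was added, of which PPARGC1A, GPX1, CYP1A4 and IL6 were not among the tested genes. The results of 1 further panel gene and of 2 genes called only under an alternative are not reported here. The genes HSPA5 and ATF4, and the genes called only under an alternative, were chosen after their values were seen.

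The scripts were tested on simulated data for PHF against control, in 10 draws of 32535 probes with 200 changed. Of probes changed by 0.5, 1, 2 and 3 on the log2 scale, 5.8%, 52.4%, 90% and 97% were recovered, with a median of 2.5 and at most 19 false calls. A list of 25 genes shifted by 0.3 was called in 10 of 10 draws and 0 of the 32 unshifted lists per draw were called. These lists were random probes, whose genes are not correlated as real lists are. Each draw shuffled group-centred values over the arrays, so the draws lack the overlap of group and slide of the real arrays. Recovery and false calls in the real data may therefore differ.

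Slide was read from the files. The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of processed signals, scaling to the array median, no filter and a filter on all 12 arrays, slide as a fixed or a random block, slide 2 alone, array weights, the replicate number as a block, each bird left out in turn, trended and robust moderation, the first residual component as a covariate, the mean of a gene's probes, and the authors' table. Leaving out controls 1 and 4, and leaving out slide 1, were added after the data were seen. After the gene ranking was seen, 4 further gene sets were also added: mitochondrially encoded genes, cytosolic aminoacyl-tRNA synthetases, the intestinal genes seen first, and further intestinal markers. The synthetases and further intestinal markers were written down before their values were looked at. Intestinal genes were read from probes well above background on at least 2 arrays.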

Results

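Transcript levels were measured in breast muscle of 12 chickens at day 42, in 6 untreated control birds and 6 birds given a polyherbal formulation (PHF), a plant-based supplement whose makeup the labels do not give. The comparison asks how the muscle transcriptome of supplemented birds differed from that of controls. The labels number the samples within each group and do not state how birds were housed, so p-values of single probes measure the spread between these samples. Camera at its preset correlation judges a list mainly by the spread between genes, taken as nearly uncorrelated. Its p-values therefore do not measure the spread between birds. Each sample was hybridised to 1 single-colour Agilent array, and the number of arrays limits the precision. The 12 arrays lay on 3 slides: slide 1 held controls 1 to 4, slide 2 held controls 5 and 6 with PHF birds 1 and 2, and slide 3 held PHF birds 3 to 6. Group and slide therefore overlapped, and the 4 arrays of slide 2 gave the comparison within a slide. Its controls were controls 5 and 6, which carried intestinal transcripts, so each value below on slide 2 or with slide as a block rests on these 2 samples as its controls. All levels below are log2 signals relative to the array's 75th percentile, given as mean ± SD with n = 6 per group.

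Calls were made for lists of genes, with small median changes, and depended on the list test used. In camera at its preset correlation, genes of cholesterol synthesis, of fatty acid and triglyceride synthesis, and of the extracellular matrix were higher in PHF birds. Genes of oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis, fast muscle contraction, cytosolic ribosomes, the proteasome, the unfolded protein and amino acid responses, the immediate early response and smooth muscle were lower. With that preset correlation between genes of 0.01, 12 of the 32 lists were called, 3 higher and 9 lower. With an estimated correlation 0 lists were called, the lowest adjusted p being 0.281, and fry, which asks whether a list's genes move one way on balance, called 1, fatty acid and triglyceride synthesis (adjusted p = 0.0128). No list had a member past the adjusted threshold over all probes. The 9579 genes tested had a median change of 0.0020, but the centre depended on brightness. Over 3 equal groups of probes the median change was 0.142 in the dimmest, 0.053 in the middle and −0.0406 in the brightest. On slide 2 these medians were 0.0164, 0.0041 and −0.0121. Camera sets each list against all other genes whatever their brightness, so its calls over all birds do not allow for this trend.

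**Figure D1:**
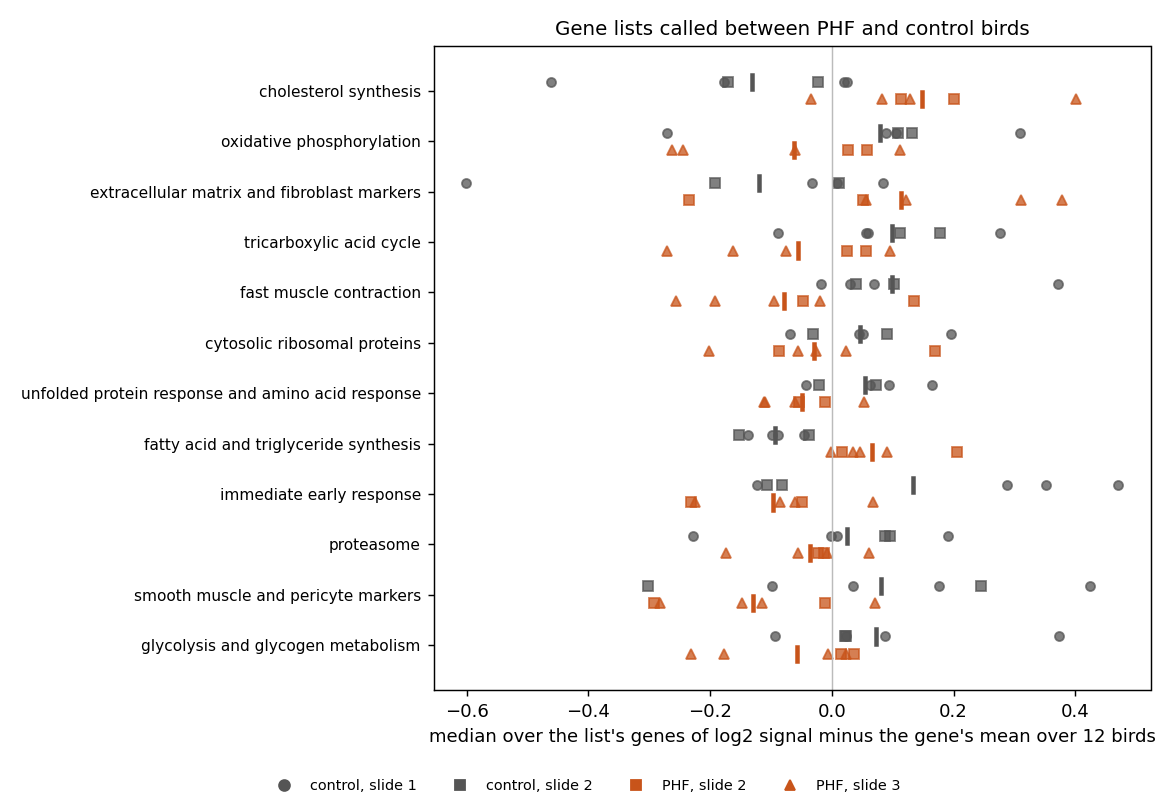
Each point is 1 bird's median, over the genes of a list, of the log2 signal minus the gene's mean over the 12 birds, for the 12 lists called by camera. Grey points are controls and orange points PHF birds, symbols give the slide and vertical bars the group mean; for fast muscle contraction control 1 lay at 0.37 and the other controls between −0.017 and 0.10.

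Sterol genes had the lowest p of the 32 lists in camera at the preset correlation, while fatty acid and triglyceride synthesis had it with an estimated correlation and in fry. Of 21 measured genes of cholesterol synthesis, 19 were higher and 2 lower in the mean of PHF birds, 10 were higher at an unadjusted p under 0.05, and 5 passed when adjusted over the list alone. The list's median was 0.25 (camera adjusted p = 7.81e-07; adjusted p = 0.52 with an estimated correlation and 0.117 by fry). IDI1, the isopentenyl diphosphate isomerase, measured 1.77 ± 0.29 in controls and 2.43 ± 0.34 in PHF birds, a ratio of 1.57. ACAT2, a cytosolic acetyl-CoA acetyltransferase, measured 1.73 ± 0.24 and 2.23 ± 0.19. DHCR7, which catalyses a last step of cholesterol synthesis, measured −1.08 ± 0.22 and −0.63 ± 0.11, and the lanosterol demethylase CYP51A1 −1.95 ± 0.27 and −1.48 ± 0.18. For each of these 4 genes all 6 PHF birds lay above the control mean, with limma's adjusted p between 0.419 and 0.473 over all probes and between 0.0201 and 0.0314 over the list alone. On slide 2 alone the list was higher with a median of 0.20 (camera adjusted p = 0.000424; 0.000474 with slide as a block). The call was kept in each of the 12 fits that left out 1 bird. The per-bird mean of the list differed by 0.279 with slide as a block. Its 95% interval of −0.117 to 0.675 spanned both directions, so the spread between birds leaves the difference within a slide undecided. On slide 2 IDI1 and ACAT2 differed by 0.84 and 0.77, but DHCR7 and CYP51A1 by only 0.16 and 0.13.

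Fatty acid and triglyceride synthesis was also called higher as a list. Of its 20 measured genes, 16 were higher and 4 lower, 2 of them higher at an unadjusted p under 0.05 and 1 past the threshold when adjusted over the list alone, SCD. SCD, the stearoyl-CoA desaturase, was dim and measured −5.17 ± 0.48 in controls, well above background on 4 of 6 arrays, and −4.24 ± 0.43 in PHF birds. FASN, the fatty acid synthase, measured 1.19 ± 0.30 and 1.56 ± 0.087, and ACLY and ACSS2, which supply cytosolic acetyl-CoA, differed by 0.26 and 0.24. All 6 PHF birds lay above the control mean for these 4 genes, and limma's adjusted p over all probes lay between 0.404 and 0.56. The list's median was 0.22 (camera adjusted p = 0.012; adjusted p = 0.281 with an estimated correlation), and on slide 2 it was 0.25 (adjusted p = 0.0603; 0.0184 with slide as a block). In the authors' processed table the list was not called (adjusted p = 0.145), and FASN and ACLY stood there at −0.40 and −0.61. Adipocyte markers, which would mark fat cells in the sample, had a median of 0.11 and were not called (adjusted p = 0.866), and FABP4 among them differed by 0.30 (adjusted p = 0.851).

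Lists of nuclear genes of mitochondrial energy metabolism were called lower at the preset correlation. Of 62 measured subunits of oxidative phosphorylation, 56 were lower and 6 higher in PHF birds, 2 lower at an unadjusted p under 0.05 and 0 past the threshold over the list alone. The median was −0.14 (camera adjusted p = 2.8e-05; adjusted p = 0.68 with an estimated correlation). NDUFV1 of complex I measured 3.17 ± 0.33 in controls and 2.76 ± 0.25 in PHF birds, UQCRQ of complex III 4.95 ± 0.23 and 4.57 ± 0.29, and COX5A of complex IV 6.25 ± 0.23 and 6.00 ± 0.13. ATP5G1, a subunit of ATP synthase, differed by −0.30. Of 22 genes of the tricarboxylic acid cycle, 18 were lower and 4 higher, 1 lower at an unadjusted p under 0.05 and 0 over the list alone, with a median of −0.16 (camera adjusted p = 0.00521; adjusted p = 0.59 with an estimated correlation). IDH3A, a subunit of isocitrate dehydrogenase, measured 5.51 ± 0.20 and 5.07 ± 0.30, and MDH1, PDHX and PDHA2 differed by −0.21, −0.25 and −0.20. Limma's adjusted p of these 8 genes lay between 0.478 and 0.609. On slide 2 the medians were −0.095 for oxidative phosphorylation (adjusted p = 0.228; 0.381 with slide as a block) and −0.087 for the tricarboxylic acid cycle (adjusted p = 0.336; 0.446 with slide as a block). Both calls ended after quantile normalization (adjusted p = 0.0791 and 0.198) and after normexp background correction with quantile normalization (0.055 and 0.258).

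Glycolysis and fast muscle contraction were lower as lists, with members in both directions. Of 34 measured genes of glycolysis and glycogen metabolism, 25 were lower and 9 higher, 2 lower and 1 higher at an unadjusted p under 0.05, and 0 passed over the list alone. The median was −0.11 (camera adjusted p = 0.0438; adjusted p = 0.68 with an estimated correlation). UGP2, which makes UDP-glucose for glycogen, measured 6.16 ± 0.22 in controls and 5.70 ± 0.22 in PHF birds, and PHKG1, the muscle phosphorylase kinase subunit, 8.95 ± 0.19 and 8.63 ± 0.23. ENO2 and LDHB, isoforms that are not the main ones of fast fibres, differed by 0.39 and 0.42, and GAPDH by −0.19. Limma's adjusted p of these 5 genes lay between 0.471 and 0.646, and GAPDH stood at 0.016 after quantile normalization. The glycolysis call ended without control 1 (adjusted p = 0.213), control 2 (0.147), control 3 (0.0758), PHF 2 (0.0508), PHF 3 (0.0969) or PHF 5 (0.121). It was absent on slide 2 (median −0.043, adjusted p = 0.946; 0.996 with slide as a block), and after scaling to the array median (0.055), quantile normalization (0.637) and normexp (0.511).

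Of 27 measured genes of fast muscle contraction, 20 were lower and 7 higher, 1 in each direction at an unadjusted p under 0.05 and 0 over the list alone. The median was −0.18 and the mean −0.063 (camera direction lower, adjusted p = 0.00521; adjusted p = 0.59 with an estimated correlation). MYLK2, the skeletal myosin light chain kinase, measured 4.31 ± 0.56 in controls and 3.44 ± 0.26 in PHF birds. MYBPC1, a myosin-binding protein C named for slow fibres, measured −5.52 ± 1.20, well above background on 4 of 6 arrays, and −3.61 ± 1.08. ACTN2 and the calcium release channel RYR1 differed by −0.23 and −0.38, ACTA1 and CKM by −0.18 and −0.19, and the myosin heavy chain MYH1B by 0.74. Limma's adjusted p of these 7 genes lay between 0.424 and 0.649. On slide 2 the list's median was −0.029 and its mean 0.048 (adjusted p = 0.966), and with slide as a block camera's direction was higher (adjusted p = 0.996). The call also ended after quantile normalization (adjusted p = 0.891) and normexp (0.847), and control 1 lay at 0.37, above the other controls. Slow and cardiac-type contraction genes had a median near 0 (0.00034) and a mean of 0.076 (adjusted p = 0.976). MB, the oxygen carrier myoglobin, differed by 0.97 (adjusted p = 0.616), with 1 of its 3 probes higher and 2 lower, and the slow myosin MYH7B by −0.33 (adjusted p = 0.9).

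The list of extracellular matrix and fibroblast markers was called higher and that of smooth muscle markers lower, both at the preset correlation. Of 47 measured genes of the extracellular matrix and fibroblasts, 40 were higher and 7 lower, 6 higher and 1 lower at an unadjusted p under 0.05, and 0 passed over the list alone. The median was 0.20 (camera adjusted p = 0.000132; adjusted p = 0.59 with an estimated correlation). VIM, the intermediate filament of mesenchymal cells, measured 6.37 ± 0.11 in controls and 6.76 ± 0.074 in PHF birds, a ratio of 1.30. The growth factor TGFB2 measured 1.13 ± 0.31 and 1.69 ± 0.17, the matrix protein DPT 0.77 ± 0.33 and 1.31 ± 0.23, and the collagen crosslinking enzyme LOXL2 −3.29 ± 0.40 and −2.71 ± 0.24. For each of these 4 genes all 6 PHF birds lay above the control mean, with limma's adjusted p between 0.338 and 0.476. On slide 2 the list had a median of 0.017 (adjusted p = 0.584; 0.831 with slide as a block), and control 1 was the lowest bird at −0.60 with the other controls between −0.19 and 0.085.

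Of 11 measured smooth muscle and pericyte markers, 10 were lower and 1 higher, 1 lower at an unadjusted p under 0.05 and 0 over the list alone, with a median of −0.20 (camera adjusted p = 0.0403; adjusted p = 0.59 with an estimated correlation). MYH11, the smooth muscle myosin heavy chain, measured −0.92 ± 0.53 and −1.45 ± 0.26, with 3 of its 6 probes lower and 3 higher. MYOCD, TAGLN and ACTG2 differed by −0.46, −0.48 and −0.28, and limma's adjusted p of the 4 lay between 0.529 and 0.698. The smooth muscle call ended without control 2 (adjusted p = 0.245), control 6 (0.0747), PHF 1 (0.149) or PHF 3 (0.0628), and on slide 2 the median was −0.13 (0.228; 0.384 with slide as a block). Endothelial markers (median −0.0089, adjusted p = 0.866), erythrocyte markers (0.061, 0.976), leukocyte and macrophage markers (−0.11, 0.248), nerve and Schwann cell markers (−0.26, 0.295) and skin and feather markers (−0.047, 0.66) were not called over all birds. The leukocyte list was called lower without PHF 5 (median −0.31, adjusted p = 5.5e-05) or control 5 (−0.21, 0.0226), and higher on slides 2 and 3 alone (0.245, 0.0458), and PHF 5 was its highest bird at 0.74. The haemoglobin gene HBAA differed by 0.16 (adjusted p = 0.784).

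The list of the unfolded protein and amino acid responses was lower by a small median, and CHAC1 differed most within it. Of 28 measured genes of the unfolded protein and amino acid responses, 20 were lower and 8 higher in PHF birds, 4 lower at an unadjusted p under 0.05, and 3 passed when adjusted over the list alone, CHAC1, ASNS and PHGDH. CHAC1, an enzyme that degrades glutathione, measured 2.73 ± 1.13 in controls and 0.21 ± 0.46 in PHF birds, a ratio of control to PHF of 5.7, and its 4 probes were all lower. ASNS, the asparagine synthetase, measured −0.19 ± 0.55 and −1.39 ± 0.46, and PHGDH, which opens serine synthesis, −1.97 ± 0.83 and −3.38 ± 0.32. VLDLR measured 4.54 ± 0.11 and 4.26 ± 0.16. The chaperone HSPA5 differed by −0.15 and the transcription factor ATF4 by −0.11, so the 3 genes that passed over the list alone were enzymes of amino acid and glutathione metabolism and not chaperones. Over all probes limma's adjusted p was 0.253 for CHAC1, 0.322 for ASNS and PHGDH, and 0.511 for VLDLR. On slide 2 the differences were −2.50 for CHAC1, −1.86 for ASNS and −0.82 for PHGDH. The list had a median of −0.10 and a mean of −0.23 (camera adjusted p = 0.012; adjusted p = 0.52 with an estimated correlation). It was not called on slide 2 (median −0.075, adjusted p = 0.0965; 0.0617 with slide as a block), after quantile normalization (0.0791) or after normexp (0.0614).

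**Figure D2:**
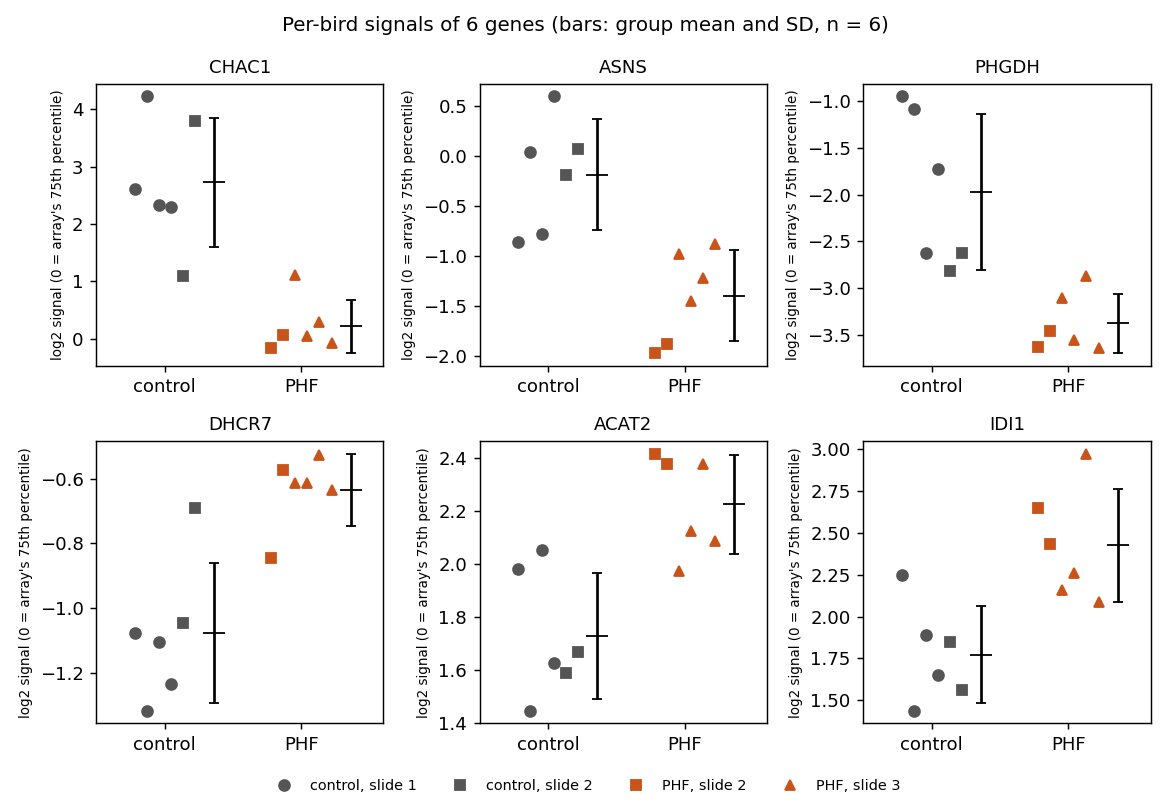
Log2 signals relative to the array's 75th percentile of CHAC1, ASNS, PHGDH, DHCR7, ACAT2 and IDI1 in each bird, with symbols for the slide and bars for the group mean and SD (n = 6). For CHAC1 the PHF birds lay between −0.17 and 1.1 and the controls between 1.1 and 4.22, and for PHGDH all 6 PHF birds lay below the lowest control at −2.82.

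The proteasome, cytosolic ribosome and immediate early lists were called lower, and the first 2 had camera direction higher after quantile normalization and after normexp. Of 38 proteasome genes, 27 were lower and 11 higher, 2 lower at an unadjusted p under 0.05, with a median of −0.065 (camera adjusted p = 0.0388; adjusted p = 0.777 with an estimated correlation). SHFM1 measured 1.87 ± 0.19 in controls and 1.52 ± 0.17 in PHF birds, and POMP, a proteasome assembly factor, −5.06 ± 0.89 and −6.16 ± 0.76, well above background on 4 and 2 arrays. The regulatory subunits PSMD6 and PSMD3 differed by −0.18 and −0.19, and limma's adjusted p of the 4 lay between 0.483 and 0.616. The proteasome call ended without control 1 (adjusted p = 0.162), control 2 (0.0578), control 3 (0.0908), control 5 (0.108), control 6 (0.0786), PHF 2 (0.0502), PHF 3 (0.0638) or PHF 5 (0.134). After quantile normalization and after normexp its camera direction was higher (adjusted p = 0.901 and 0.85), and on slide 2 its median was −0.11 (0.0603; 0.043 with slide as a block). Of 64 cytosolic ribosomal protein genes, 44 were lower and 20 higher, none at an unadjusted p under 0.05, with a median of −0.072 (camera adjusted p = 0.00607; adjusted p = 0.777 with an estimated correlation). RPL8, RPL35, RPL9 and RPS20 each differed by −0.20, with limma's adjusted p between 0.562 and 0.597, and 2 of 3 probes of RPL8 and of RPL9 were higher. The ribosomal call ended without PHF 5 (adjusted p = 0.134) and on slide 2 (median −0.00095, 0.966; 0.996 with slide as a block). Its camera direction was higher after quantile normalization (0.233) and normexp (0.055). In both lists 0 genes passed over the list alone.

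Of 24 immediate early genes, 19 were lower and 5 higher, 3 lower and 1 higher at an unadjusted p under 0.05 and 0 over the list alone, with a median of −0.26 (camera adjusted p = 0.0133; adjusted p = 0.59 with an estimated correlation). CSRNP1 measured 1.45 ± 0.31 in controls and 0.87 ± 0.33 in PHF birds, the matricellular gene CCN2 1.87 ± 0.83 and 1.07 ± 0.36, and the phosphatase DUSP6 1.26 ± 0.21 and 0.88 ± 0.33. MYC, a growth-related transcription factor, measured −2.02 ± 0.41 and −1.48 ± 0.39, and limma's adjusted p of the 4 lay between 0.473 and 0.532. The immediate early call ended without control 1 (adjusted p = 0.0519), control 2 (0.104) or control 4 (0.0578), and without controls 1 and 4 together (0.311). On slide 2 the median was 0.0077 (0.946; 0.996 with slide as a block).

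Lists of antioxidant, detoxifying, heat shock and immune genes were not called over all birds. Antioxidant and NRF2 target genes had a median of −0.033 (adjusted p = 0.295), with 17 of 41 higher, and among them NFE2L2, the regulator of this response, differed by −0.031, HMOX1 by 0.39 and SOD1 by −0.10 (adjusted p = 0.936, 0.762 and 0.785). Xenobiotic metabolism had a median of 0.035 and a mean of −0.026 (adjusted p = 0.861), and 1 gene lower passed over that list alone. Heat shock proteins had a median of 0.066 (adjusted p = 0.271), with HSPA8 at 0.21, and were called higher after quantile normalization (adjusted p = 0.0267), after normexp (0.0113) and in the authors' processed table (0.0336). Interferon response genes (median 0.094, adjusted p = 0.544) and inflammatory cytokines and toll-like receptor signalling (−0.018, 0.66) were not called, and IL1B and MX1 differed by 0.14 and 0.046 (adjusted p = 0.861 and 0.991). PHF 5 lay at 1.62 for the interferon list, with the other PHF birds between −0.50 and 0.12, and at 2.83 for MX1 with the others between −4.53 and −1.22. The interferon list was called lower without PHF 5 (median −0.23, adjusted p = 0.0166), higher without controls 1 and 4 (0.38, 0.0185) and on slides 2 and 3 alone (0.415, 0.0398), and its median on slide 2 was −0.13 (adjusted p = 0.228).

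Growth and protein breakdown lists were not called over all birds either. Myogenic regulation and growth signalling had a median of −0.026 and a mean of 0.024 (adjusted p = 0.866). Within it MSTN, which restrains muscle growth, differed by 0.31, IGF1 by 0.64 and the growth hormone receptor GHR by −0.052 (adjusted p = 0.617, 0.576 and 0.899). Muscle protein breakdown and autophagy had a median of −0.041 (adjusted p = 0.194), and its ubiquitin ligases FBXO32 and TRIM63 differed by −0.032 and −0.00047 (adjusted p = 0.985 and 1). Fatty acid oxidation had a median of −0.0047 (adjusted p = 0.761), with PDK4 at −0.74, CPT1A at −0.13 and UCP3 at −0.13 (adjusted p = 0.559, 0.832 and 0.905). The remaining lists, not called over all birds, were mitochondrial ribosomal proteins (median −0.050, adjusted p = 0.142), cell cycle (0.077, 0.271), insulin signalling and glucose uptake (0.020, 0.861), amino acid transport and metabolism (−0.068, 0.271), and calcium handling and excitation (−0.074, 0.196). Mitochondrial ribosomal proteins were called lower without control 4 (0.000713), PHF 1 (0.0443) or controls 1 and 4 together (0.00243), and cell cycle higher without PHF 6 (0.0039). Beta-actin, ACTB, differed by −0.27 (adjusted p = 0.559).

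No single probe passed the test. Limma called 0 of 32535 probes higher and 0 lower, with a lowest adjusted p of 0.253, and 2921 stood at an unadjusted p under 0.05 where 1627 would be given by chance. Of these 1943 were higher, 1167 of them among the dimmest of 3 equal groups of probes, and 978 lower, 462 of them among the brightest, a split of 1452 and 1108 after quantile normalization, 1306 and 1209 after normexp, and 1467 and 1347 after scaling to the array median. Among the genes of lowest p, none past the threshold, PAPSS2, which makes the sulphate donor, measured −1.81 ± 0.14 in controls and −1.16 ± 0.16 in PHF birds, though its other probe was lower. PGM3 and the mesenchymal transcription factor TCF21 differed by 0.94 each, and NRN1, OLFM1, AvBD4, PPP4R1L and NHLH1 by 1.13, 0.70, 0.69, 0.52 and 0.50. ZIC2 and GUCA1B differed by 1.15 and 1.6 and were well above background on 1 and 2 control arrays and on 6 PHF arrays each. On the lower side, CHAC1 and ASNS stood beside ANGPTL6 at −1.35, the cytokinesis regulator RACGAP1 at −1.25, the neuronal gene STMN2 at −1.06, PDE4B at −0.69, ORAOV1 at −0.62 and RNF207 at −0.60. SPOCK3 differed by −2.33 and PAX2 by −2.03, well above background on 6 control arrays each and on 1 and 2 PHF arrays. The adjusted p of these 20 genes lay between 0.253 and 0.322, and all 6 PHF birds lay on 1 side of the control mean for each. Genes of lowest p, here and in the lists above, were picked on these same values, so such counts of birds add no separate support. On slide 2 PAX2 differed by −0.055 and AvBD4 by 0.27, while ANGPTL6 differed by −1.88 and SPOCK3 by −2.37.

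With slide as a fixed block limma called 4 probes lower, TM4SF4, CDH1, APOA4 and 1 transcript without a gene name, which were high in controls 5 and 6 (745 probes at an unadjusted p under 0.05, fewer than the 1627 that chance would give). TM4SF4 measured 0.39 and −1.43 in these controls against a mean of −5.47 in slide 1 controls, and APOA4 4.10 and 2.46 against −0.74. These genes were chosen after their values were seen. With the same block the skin and feather list, which holds the epithelial genes CDH1 and EPCAM, was called lower (median −0.39, adjusted p = 0.0297). Slide as a random block, array weights, trended and robust moderation, and a covariate for the first residual component each called 0. Within groups, slides differed too: PHF birds of slide 3 had 146 probes higher and 14 lower than those of slide 2, and controls of slide 2 had 0 called against those of slide 1 (1853 at an unadjusted p under 0.05).

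Controls varied more from bird to bird than PHF birds. The median SD over probes was 0.353 in controls and 0.250 in PHF birds, 72.2% of probes had the higher SD in controls, and the median log2 ratio of variances, PHF over control, was −0.90. Among 100 random splits of the group-centred values the permutation p was 0.0396. The result ended without control 1 (ratio −0.55, permutation p = 0.188), control 4 (−0.57, 0.129) or PHF 2 (−0.99, 0.0594), and without the 4 arrays of slide 1 the ratio was 1.28 (0.276). The first principal component, 22.0% of the variance, set control 1 apart. The second, 15.6%, set control 4 apart and slide 2 from slide 3, with 53.6% of its variance between slides and 0.669% between groups. Components 1, 3 and 4 had 44.5%, 46% and 45.5% of their variance between slides, and 24.7%, 13.2% and 31.7% between groups.

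**Figure D3:**
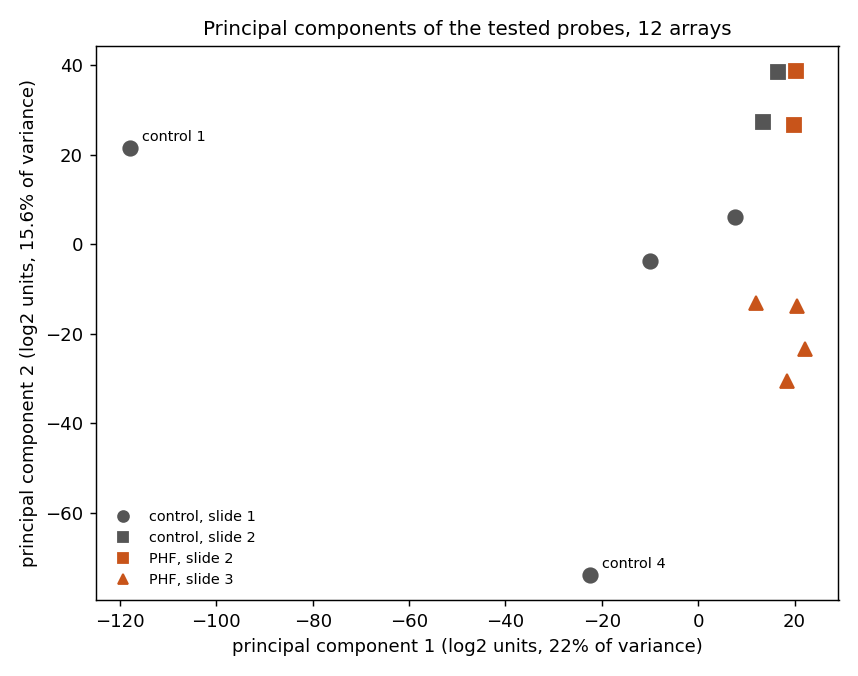
Scores of the 12 arrays on the first 2 principal components of the tested probes, in log2 units, with colour for the group and symbol for the slide. Control 1 lies apart on component 1 and control 4 on component 2, and the 4 arrays of slide 2, from both groups, lie together.

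Arrays of PHF birds also measured more probes. The share of probes well above background was 72.3% ± 3.8 in controls and 76.8% ± 1.6 in PHF birds (n = 6 each, two-sided exact permutation p = 0.0216, adjusted p = 0.0288 over 4 measures). It was 70.2% in slide 1 controls, 76.6% in slide 2 controls, 75.7% in slide 2 PHF birds and 77.3% in slide 3 PHF birds, so the difference was not seen on slide 2. Median background was 20.3 ± 1.8 and 23.1 ± 0.66 (exact permutation adjusted p = 0.0288), and 22.5 in both groups on slide 2. The mean correlation with arrays of the own group was 0.9727 ± 0.0051 in controls and 0.9821 ± 0.0011 in PHF birds. Its exact permutation p of 0.00216 (adjusted p = 0.00864) is not a valid test, since arrays of a group share pairs. For the arrays of slide 2 it was 0.9762 and 0.9814, averages that include partners on other slides. Between pairs of slide 2 arrays the mean correlation was 0.9865 within groups and 0.9859 between groups. The 75th percentile of signal was 413.1 ± 35.8 and 453.9 ± 53.4 (exact permutation p = 0.143), and pairs of arrays correlated between 0.9604 and 0.9871.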

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

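The check for single birds far from their group was fixed before the data were examined, and no test here was chosen after the result was seen. In 21 of 210 groups of 6 values, 1 bird stood apart from the others by more than Dixon's critical gap, where chance gives about 1 in 20 groups, 10.5 of 210. Control 1 was that bird 6 times, PHF 1, PHF 2 and PHF 4 were 3 times each, control 4 was 2 times, and controls 3 and 6 and PHF 3 and PHF 6 were 1 time each. The check covered the named genes, the called lists and the array measures. The interferon list, where PHF 5 lay at 1.62, was not called and so was not checked. The groups of values share arrays and are not independent, and no explanation was tested.

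Control 1 read 7.82 for ATP5G1 with the other controls between 7.16 and 7.33, 4.90 for PSMD6 with the others between 4.41 and 4.57, and −0.92 for STMN2 with the others between −2.02 and −1.64. It read −1.91 for MYOCD with the others between −3.63 and −3.17, 0.55 for TGFB2 with the others between 1.12 and 1.43, and 0.37 as its median over fast muscle contraction genes with the others between −0.017 and 0.10. Control 4 read −5.41 for PPP4R1L with the others between −4.97 and −4.83, and −1.25 for MYC with the others between −2.437 and −1.996. Control 3 read 1.42 for UCP3 with the others between 2.49 and 2.82, and control 6 read 0.34 for HBAA with the others between −0.66 and −0.33.

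Among PHF birds, PHF 2 read −5.75 for MYBPC1 with the others between −3.59 and −2.90, 4.96 for MYH1B with the others between 6.55 and 6.87, and −5.39 for IGF1 with the others between −4.55 and −4.18. PHF 1 had 73.6% of probes well above background with the others between 76.6% and 77.8%, and read 1.40 for FASN with the others between 1.56 and 1.64, and −0.85 for DHCR7 with the others between −0.63 and −0.52. PHF 4 read −4.03 for ZIC2 with the others between −5.41 and −4.93, −4.73 for NRN1 with the others between −3.86 and −3.41, and 6.25 for COX5A with the others between 5.86 and 6.01. PHF 3 read 1.101 for CHAC1 with the others between −0.17 and 0.29, and PHF 6 read 0.22 for DUSP6 with the others between 0.92 and 1.07.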

How the results depend on the processing

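The fits without controls 1 and 4 and those on slides 2 and 3 alone were chosen after the data were seen. The count of probes past the adjusted threshold was 0 and stayed 0 after quantile normalization, normexp, scaling to the array median, the filter on all 12 arrays, slide as a random block, array weights, trended and robust moderation, the residual component and without controls 1 and 4. Without a filter 2 were called, both lower (LOC100859072 and ISL1), with slide as a fixed block 4, on slide 2 alone 1, on slides 2 and 3 alone 7 (among them TM4SF4, CDH1, APOA4, B-G, MEP1A and FABP1), and in the authors' table there was 1 (AACS at −2.8), all of them lower. Leaving out 1 bird gave 0 to 1, the 1 being higher and without a gene name, without control 5. LOC100859072 was well above background on 0 control and 0 PHF arrays, and ISL1 on 4 control and 0 PHF arrays. The table's AACS went from 0.854 to −1.95 while its 2 probes on the scanner went from 0.322 to 0.594 and from −6.61 to −5.63, so that call has no counterpart in the signals. The cause of the other differences was not tested.

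Against 12 lists called, 6 were called after normexp and 6 after quantile normalization (5 among the 12 in each case), 4 with slide as a fixed block and 4 with the authors' values (3 among the 12 in each case), 1 on slide 2 alone (cholesterol synthesis), 1 by fry and 0 with an estimated correlation. The count was 11 after array-median scaling, a random block (all 11 among the 12 in both) and array weights (10 among the 12), 9 without a filter and with the filter on all 12 arrays (all 9 among the 12), 13 with the mean of a gene's probes and without controls 1 and 4 (11 among the 12 in each), and 10 on slides 2 and 3 alone (7 among the 12). Leaving out 1 bird gave 8 to 13. Mitochondrial ribosomal proteins were also called with array weights (adjusted p = 0.0123), with the mean of a gene's probes (0.0323) and on slides 2 and 3 alone (0.00796), and muscle protein breakdown with the mean of a gene's probes (0.0403). Slides 2 and 3 alone ended the calls for glycolysis (adjusted p = 0.535), cytosolic ribosomal proteins (0.0813), smooth muscle (0.427), the unfolded protein and amino acid responses (0.0539) and immediate early genes (0.764). Cholesterol synthesis was called in every list fit listed here except with an estimated correlation and by fry. Slide 2 alone held 2 birds per group, fewer samples by construction, with controls 5 and 6 as its controls, and slide as a block takes its value from that slide. The ratio of variances was −0.897; with the filter on all 12 arrays it was −0.854 (permutation p = 0.0594), leaving out 1 bird gave −1.08 to −0.554, and on slides 2 and 3 alone it was 1.28. A signal close to background limits the dim genes: SCD, TCF21, ZIC2, GUCA1B, PPP4R1L, NHLH1, ANGPTL6, SPOCK3, PAX2, POMP, MYBPC1, MYH7B, IGF1 and IL1B were not well above background on every array.

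Directions turned as follows, and the cause was not tested. After normexp the median of the proteasome list was −0.00724 with camera's direction higher, that of ribosomal proteins 0.025, and ACTA1 stood at 0.0758, GHR at 0.0434, FBXO32 at 0.053, TRIM63 at 0.057, CPT1A at 0.00448 and SOD1 at 0.0283. After quantile normalization the proteasome list had a median of 0.0139 and ribosomal proteins 0.0373, with GAPDH at 0.0156, GHR at 0.00287, TRIM63 at 0.0733 and SOD1 at 0.00619. With slide as a block, and equally on slide 2 alone, RYR1 stood at 0.133, RPS20 at 0.0263, TAGLN at 0.0718, ACTA1 at 0.138, MYH7B at 0.371, TRIM63 at 0.183, CPT1A at 0.108, UCP3 at 0.377, FABP4 at −0.231, SOD1 at 0.0344, IL1B at −0.289 and MX1 at −1.05. With the block the fast muscle list had a median of −0.0287 with camera's direction higher, and on slide 2 alone the immediate early list had a median of 0.00772. On slides 2 and 3 alone the immediate early list had a median of −0.0143 with camera's direction higher, and PDHX stood at 0.00711, TAGLN at 0.192, ACTG2 at 0.17, GAPDH at 0.0441, MYH7B at 0.719, FBXO32 at 0.541, TRIM63 at 0.0756, IL1B at −0.266 and HBAA at −0.131. In the authors' table FASN stood at −0.398, ACLY at −0.605, RPL8 at 0.065, GHR at 0.274, FBXO32 at 0.0954, TRIM63 at 0.148 and MX1 at −0.168. FBXO32 and TRIM63 stood at 0.0941 and 0.011 with array weights and at 0.0857 and 0.0257 without controls 1 and 4, and TRIM63 at 0.00658 with a random block. Leaving out 1 bird gave −0.00122 to 0.312 for IL1B, −0.0811 to 0.0124 for NFE2L2, −0.669 to 0.205 for MYH7B, −0.362 to 0.0261 for UCP3, −0.935 to 0.537 for MX1, −0.214 to 0.219 for FBXO32 and −0.0763 to 0.0848 for TRIM63. None of these genes passed the threshold in any of these fits.

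Both groups carry replicate numbers 1 to 6, and the labels do not say whether the numbers pair the birds. Of the 6 pair correlations 0 exceeded 0.1, with a range of −0.22 to 0.074. Only 1 of 6 controls correlated best with the PHF bird of its own number. Birds of the same number never shared a slide, so these correlations cannot exclude a pairing. With the replicate number as a block 2 probes were called, 1 higher and 1 lower and neither with a gene name, and 12 lists.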

Other observations

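The tests of slides and of a single bird for CHAC1, ASNS and PHGDH, of slides and of mitochondrial content for mitochondrially encoded genes, of dim probes, and the counts of splits for adjusted probes and for the lowest p of a list were chosen after the result was seen. In contrast to the nuclear subunits, transcripts of the mitochondrial genome were higher in PHF birds. Of 34 probes for the 13 protein genes, 32 were higher, 27 of them at an unadjusted p under 0.05, and 1 was lower at that level. Read by 1 probe per gene, 11 of the 13 were higher, 10 of them at that level, and 1 was lower at that level. Probes of a gene share birds and are not independent. The per-bird mean of the 13 genes was 5.33 ± 0.28 in controls and 5.78 ± 0.089 in PHF birds, a difference of 0.45 (95% interval 0.19 to 0.72, n = 6, exact permutation p = 0.00866). Probes of CYTB, ND1 and ND3 differed by 0.62 to 0.83, by 0.72 to 0.83 and by 0.71 to 0.77, while the brightest probes of COX2 and COX3 stood at −0.23 and −0.092. Camera gave p = 2.16e-08 for this set, p = 1.7e-06 with slide as a block and p = 0.0208 with an estimated correlation, outside the adjustment over 32 lists. The set was written after the gene ranking was seen and is no independent evidence of its direction.

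Controls 5 and 6 carried transcripts of intestinal epithelium that the other 10 birds did not show at that level. FABP1, the fatty acid binding protein of liver and gut, read 2.86 and 1.74 in these birds and at most −2.43 in the other 10, and the apolipoprotein APOA4 read 4.10 and 2.46 against at most −0.62. The epithelial adhesion gene EPCAM read −1.02 and −2.86 against at most −7.21, the gut transcription factor CDX2 −1.61 and −2.81 against at most −3.61, and RBP2 −0.20 and −1.56 against at most −5.75. Of 15 such genes, chosen after their values were seen, 14 were above all other birds in both controls, with a median difference of 4.59 from the PHF birds of the same slide. Of these 15, 5 were well above background on all 12 arrays, so the size of the difference is approximate for the others.

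For the lower CHAC1, ASNS and PHGDH, the per-bird mean of the 3 genes was 0.19 ± 0.61 in controls and −1.52 ± 0.34 in PHF birds, a difference of −1.71 (95% interval −2.34 to −1.08, n = 6, exact permutation p = 0.00216, on genes picked because they differ). With slide as a block the difference was −1.73 (95% interval −2.83 to −0.623), a value that rests on controls 5 and 6. Leaving out 1 bird gave −1.54 at the weakest, without control 2. Both values come from genes picked on the same birds, so they do not exclude a difference between slides or a single bird as the cause. For these 3 genes the difference was seen on slide 2 and in each fit that left out 1 bird. A lower amino acid response in PHF birds is a hypothesis that may account for it: of 17 cytosolic aminoacyl-tRNA synthetases, further targets of that response, 16 were lower, with a median of −0.127, a per-bird difference of −0.16 (exact permutation p = 0.0974), which was −0.0829 without control 1, and camera p = 0.00169, the last of which met the prediction written beforehand. It is left open because the p was 0.181 with an estimated correlation, a requirement added after the values were seen, and because the median on slide 2 was 0.011.

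For the higher mitochondrially encoded transcripts, the difference was seen in each fit that left out 1 bird, the weakest being 0.359 without control 1. The set was written after the ranking of these same birds was seen, so this does not exclude a single bird as the cause. A difference between slides stays open, since with slide as a block the difference was 0.393 with a 95% interval of −0.137 to 0.923, although 32 of 34 probes were higher on slide 2 too, and the means were 5.320 and 5.352 in controls of slides 1 and 2 and 5.745 and 5.80 in PHF birds of slides 2 and 3. More mitochondria per fibre, with nuclear subunits rising in proportion, is left open. Over all birds, where group and slide overlap, the values go against it. The nuclear oxidative phosphorylation genes had a median of −0.143, called lower by camera at the preset correlation. That call was lost with an estimated correlation (camera adjusted p = 0.68) and with slide as a block (0.381). Their per-bird mean differed by −0.13 with a 95% interval of −0.346 to 0.0872, below the lower limit of 0.185 for the mitochondrially encoded genes. With slide as a block the nuclear interval was −0.465 to 0.354, which overlaps that of −0.137 to 0.923, so these values cannot decide. The bound on the interval was set after the values were seen. Other biological explanations of this rise were not tested.

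For the intestinal transcripts of controls 5 and 6, a difference between slides is argued against: over 24 further intestinal markers PHF birds of slide 2 differed from those of slide 3 by a median of −0.109, while slide 2 controls exceeded slide 1 controls by 0.506. RNA of intestinal epithelium in these 2 samples is a candidate explanation that the test left open, since the further markers were higher by a median of 0.422 than in the PHF birds of slide 2, short of the 1 set beforehand. Of the 24, 8 were over 1 higher and 5 were above the other 10 birds in both controls, among them GPA33, at −1.72 and −3.24 against at most −6.01, and 14 were well above background on all 12 arrays. No other explanation was tested, and the labels give breast muscle for both samples.

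Among 100 of the 462 splits of the 12 arrays into 6 and 6, the real one included, 100 gave at least the 0 probes past the adjusted threshold, which any split must, so this count tests nothing; the highest other gave 9. For probes at an unadjusted p under 0.05, 5 splits gave at least the real 2921, the highest other giving 3404, so chance was not excluded. In the 4 others slide 2 and slide 3 lay mostly on opposite sides. With slide as a block 745 probes stood at that level, fewer than the 1627 that chance would give. For called lists 6 splits gave at least 12, the highest other 15, so chance was not excluded either. The other splits called a median of 6 lists, so camera at the preset correlation also called lists between arbitrary groups of these arrays. For cholesterol synthesis 3 splits gave as small a camera p as the real one, 2.44e-08, the smallest other being 1.22e-08, but the list was picked as the lowest p of 32, so this count does not exclude chance. Taking the lowest camera p over the lists in each split, 63 splits gave one as small, the smallest other being 2.69e-25, so chance was not excluded. Over the dimmest of 3 equal groups of probes the median change was 0.142 over all birds and 0.0164 on slide 2, and over the brightest −0.0406 and −0.0121, with 1167 of the 1943 unadjusted higher probes in the dimmest group.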
